A study of Mus musculus with 6 samples.

How the data were processed

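Messenger RNA was measured on 6 Affymetrix mouse arrays. Each array held RNA pooled from the type II alveolar epithelial cells of 3 mice aged 8 weeks, per the labels' protocols. Type II cells make and secrete pulmonary surfactant. In 3 pools the mice carried a conditional Gpr116 allele together with a surfactant protein C driven, doxycycline-dependent Cre recombinase. The other 3 pools came from mice with the same Cre transgenes and no conditional allele, so both groups carried Cre. Groups and replicate numbers were taken from the array titles. The other numbers in the titles are not explained in the labels. The first of them was 9, 9 and 11 on the arrays labelled knockout and 8, 8 and 10 on the control arrays. No first number was shared between the groups. If it marks a batch, that batch cannot be told apart from the group. The labels describe the pooled mice as matched for sex and age. Adjusted p values here set group differences against the spread between pools of mice, not between single animals.

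The deposited values are log2 expression values made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA subtracts background, makes the distributions of the arrays alike and summarises the probes of a probe set. A difference shared by most genes would therefore be removed before deposit, and differences of very bright genes are compressed near the top of the scale. The table holds values to 2 decimals for 35556 probe sets. Array medians lay between 6.77 and 6.81 and array maxima between 13.32 and 13.43. The number of arrays limits the precision of every value. The genome build behind the array is not given in the sources used here, so no coordinates are printed.

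Probe sets were named through the platform annotation. Of them 21789 had 1 gene symbol, 1621 had several and 12146 had none. Of the 1-symbol probe sets 21698 matched a mouse RefSeq gene table (GRCm38.p6) by Entrez identifier, and 0 symbols changed. Where a gene had several probe sets, as 999 did, the one with the highest mean over the 6 arrays was used, which left 19938 genes. Among 105 called genes with several probe sets, 9 had probe sets that disagreed in direction. List members without a 1-symbol probe set were not analysed here.

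The arrays labelled knockout were compared with the control arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. No filter, weight or block was used. Before the data were examined, 27 gene lists were fixed, covering surfactant and lipid metabolism, signalling and stress, 9 other cell types, and the genes that neighbour Gpr116. They were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the 27 lists. Camera was repeated with the correlation estimated from the data, and fry, a rotation test, was run on each list. The lists share 9 genes. Counts of list members are given over all genes tested and adjusted over the list alone. The genes to be named were also fixed beforehand. They were the 12 with the largest log2 difference in each direction among called genes, without predicted and clone symbols, then Gpr116, P2ry2 and up to 4 members of each list with the smallest p. P2ry2 was picked from general knowledge of this field and of the study, so its result does not test an independent prediction. Any other gene named was chosen after its values were seen.

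Both tests were first tested on simulated data with the spread of each gene pooled over both groups. Among 19938 simulated genes, 58 of 100 changed by 0.5 on log2 were recovered, and 90 of 100 changed by 1. Of these 0 had the wrong direction, and 7 unchanged genes were called. Camera with the preset correlation called 0 of 100 simulated lists of 20 genes without a shift and 100 of 100 with a shift of 0.3. Genes in these simulations were independent, unlike genes of a pathway. Each simulated gene also had the same spread in both groups. In the data the median SD was 0.0907 on the arrays labelled knockout and 0.0625 on the control arrays. The simulations do not check the tests under such unequal spread.

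Replicate numbers are shared by both groups, and the labels do not say what they mark. Deviations from the group mean correlated at 0.192, 0.103 and 0.111 between arrays of the same number over the tested genes. These exceeded the 0.1 set beforehand as the limit for treating the numbers as pairs. Over all probe sets the values were 0.227, 0.0380 and 0.106. There knockout 2 correlated more closely, at 0.141, with a control array of another number. For numbers 1 and 3, and for each number over the tested genes, the same-number value was the higher. Array pairs 1 and 2 each joined a male and a female pool, judged by Xist and the Y-linked genes Kdm5d, Eif2s3y and Uty. The pairing therefore rests on the values alone and is weak. A fit with the number as a block is quoted beside results whose calls it changed, and the other list members it changed are named with the alternatives.

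Alternatives covered filters on dim probe sets at the 40th and 60th percentile, an intensity trend with robust fitting, array weights, blocks on the replicate number and on the title numbers, quantile normalization again, median centring, other treatments of several probe sets, other thresholds, and leaving out each array. A block on the sex of the pools and a fit of the female pools alone were added after seeing the data.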

Results

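Gene expression was measured in type II alveolar epithelial cells, the surfactant-producing cells of the lung, from mice meant to lack the adhesion receptor Gpr116 in these cells and from control mice. Each of the 6 arrays held RNA pooled from 3 mice aged 8 weeks, with 3 pools per group. The comparison asked how deletion of Gpr116 changes the transcripts of these cells. Correlations between arrays over the tested genes were 0.996 to 0.998 among control arrays, 0.988 to 0.993 among arrays labelled knockout and 0.987 to 0.990 between groups. The median standard deviation of a gene was 0.0907 on the arrays labelled knockout and 0.0625 on the control arrays. One pool in each group was male by Xist and Y-linked genes, namely knockout 2 and control 1, and the other 2 in each group were female.

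The probe set for Gpr116, now named Adgrf5, was not lower on the arrays labelled knockout. It read 11.89, 11.78 and 11.87 there and 11.49, 11.53 and 11.51 on the control arrays, a log2 difference of 0.34 ± 0.05 (SE, n = 3 per group; limma adjusted p = 0.0119). The gene had 1 probe set, and where its probes lie relative to the deleted part is not known here, so it does not check the genotype. All directions below rest on the labels, and arrays are called labelled knockout for that reason. The Gpr116 call was lost without control 1, control 2 or control 3, with adjusted p of 0.0611, 0.0596 and 0.0648. Of 15 measured genes that neighbour Gpr116, 0 passed the limma threshold over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. Camera gave adjusted p = 0.314 for these neighbours. The closest were Pla2g7 at -0.50 ± 0.12 (adjusted p = 0.0556, but 0.0139 without knockout 2 and 0.0208 with the replicate number as a block) and Clic5 at -0.38 ± 0.10 (adjusted p = 0.0668). Without knockout 1, 1 neighbour passed, lower.

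P2ry2, the purinergic receptor through which extracellular nucleotides stimulate surfactant secretion, was 2.15-fold higher on the arrays labelled knockout (8.68 ± 0.13 against 7.58 ± 0.11 on log2, SD, n = 3 each, with an SE of 0.09 for the difference; limma adjusted p = 0.00371). This gene had been picked with knowledge of the study. The ion channel receptor P2rx5 rose by 0.49 ± 0.06 and P2rx6 fell by 0.78 ± 0.08 (adjusted p = 0.00601 and 0.00487). On the purinergic and adenosine receptor list, no adenosine receptor gene was among the tested genes. Of the 15 measured members, all purinergic receptors, P2ry2 and P2rx5 rose, P2rx6 fell and 12 did not pass. Adjusted over the list alone, 2 were higher and 1 lower. With the replicate number as a block P2ry14 (0.28 ± 0.15, adjusted p = 0.339) also passed, at 0.0488. As a list they did not pass camera (adjusted p = 0.488). P2rx6 was highest on knockout 1 and lowest on knockout 3 of its group, as was the mean of the ciliated cell markers.

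**Figure D1:**
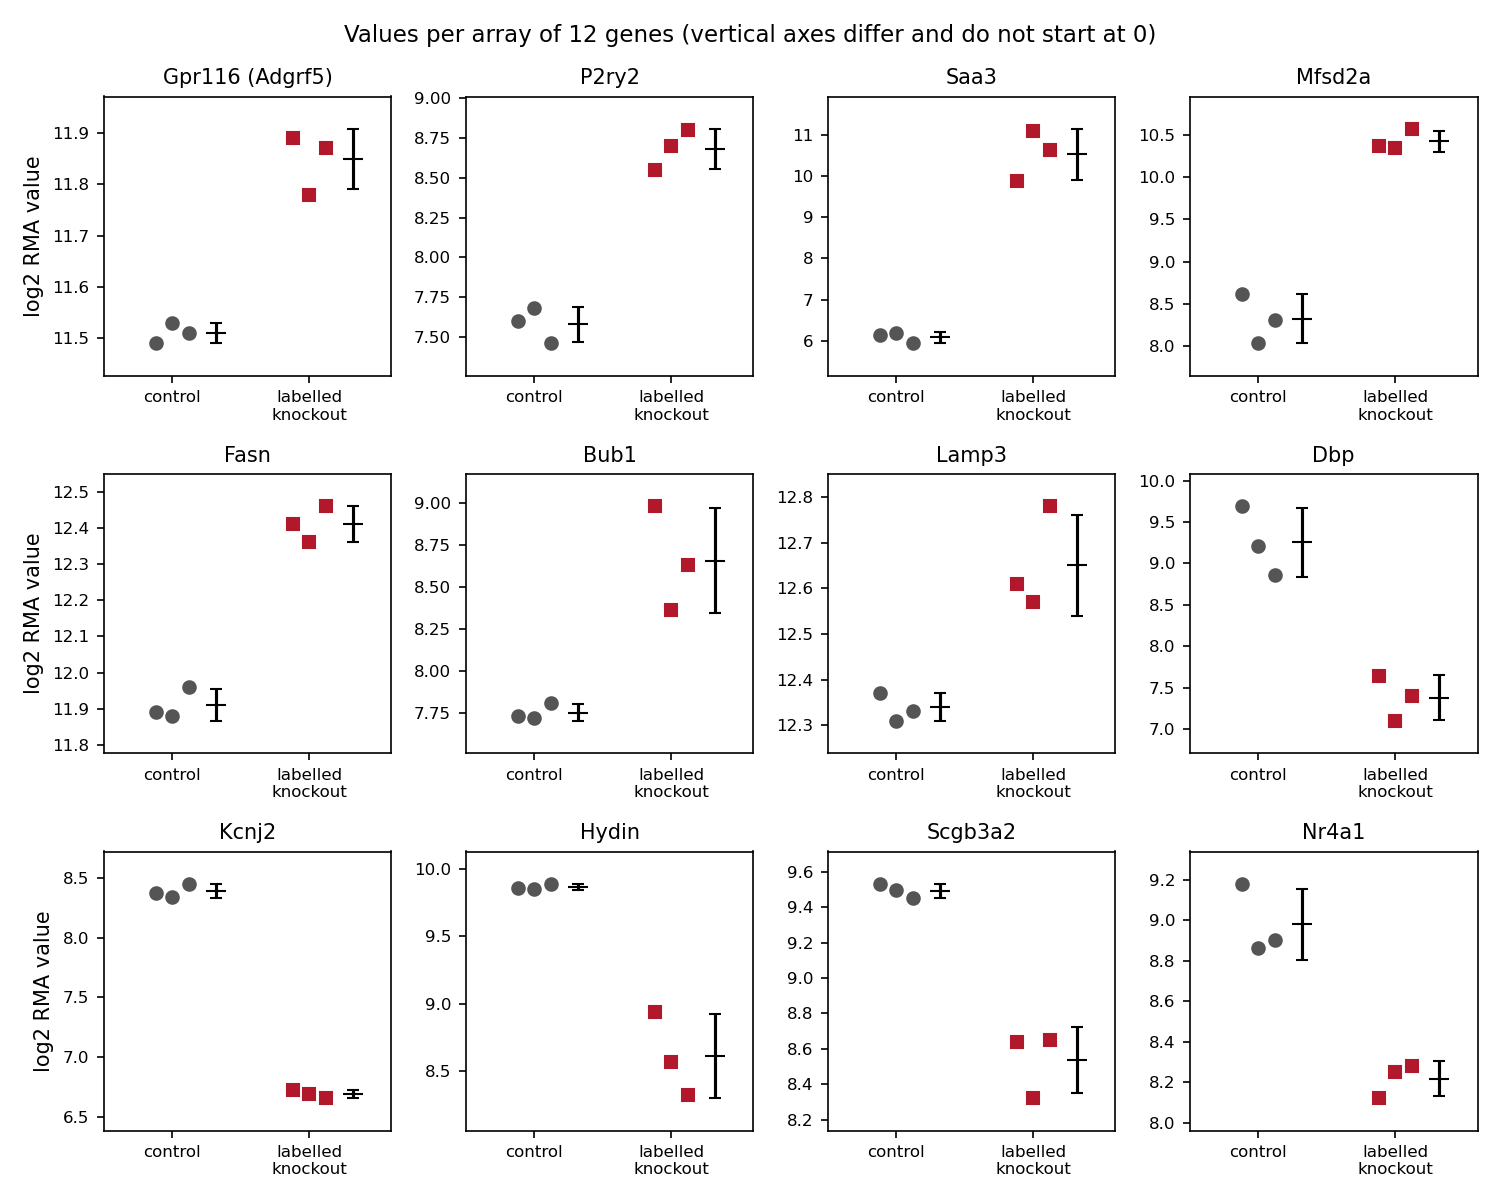
Values per array of 12 genes on the deposited log2 scale, with grey circles for control pools, red squares for pools labelled knockout, and bars for the mean ± SD of 3 arrays. The vertical axes differ and do not start at 0. Gpr116 read 11.78 or more on each array labelled knockout and 11.53 or less on each control array.

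The largest rise was that of Saa3, an acute phase serum amyloid protein, at 4.45 ± 0.28 on log2 (21.8-fold; limma adjusted p = 0.00187). Next came Cxcl13, a B cell chemokine, at 2.89 ± 0.25, the anion exchanger Slc26a4 at 2.33 ± 0.11, the fibrinogen chain Fgg at 2.19 ± 0.20 and the lysophospholipid transporter Mfsd2a at 2.10 ± 0.15. The secreted glycoprotein Lrg1 rose 4.01-fold (log2 SE 0.16), the resistin-like protein Retnla by 1.74 ± 0.10, the metalloproteinase inhibitor Timp1 by 1.69 ± 0.30 and the IgE receptor Fcer2a by 1.66 ± 0.18. The imprinted noncoding RNA Meg3 (1.51 ± 0.07), the fibrinogen-like protein Fgl1 (1.48 ± 0.18) and the metalloreductase Steap4 (1.38 ± 0.18) completed the 12 largest rises. Adjusted p values of these genes ran from 0.000639 to 0.0188.

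Among genes that fell, the circadian transcription factor Dbp changed most, at -1.87 ± 0.22 on log2 (3.66-fold lower; limma adjusted p = 0.00547). The inward rectifier potassium channel Kcnj2 fell by 1.69 ± 0.05, the potassium channel interacting protein Kcnip4 by 1.52 ± 0.10, the potassium channel Kcnk2 by 1.39 ± 0.18 and Lrrc26, an auxiliary subunit of a potassium channel, by 1.38 ± 0.21. The esterase Ces1g fell by 1.68 ± 0.27, the aldehyde oxidase Aox3 by 1.38 ± 0.20 and the scaffold protein Cnksr2 by 1.38 ± 0.22. The remaining 4 were Adgb (-1.42 ± 0.16), Bbof1 (-1.35 ± 0.13), Ccdc170 (-1.34 ± 0.12) and Cfap44 (-1.33 ± 0.12), of which Bbof1 and Cfap44 are named for basal bodies and cilia. Of the 12 genes, all but Dbp stood highest on knockout 1 and lowest on knockout 3, as did the mean of the ciliated cell markers given below (8.79, 8.38 and 8.23 on knockout 1, 2 and 3). Of the 24 genes 19 kept their calls whichever array was left out. Timp1, Ces1g, Lrrc26 and Cnksr2 lost theirs without control 1, control 2 or control 3 and Aox3 without control 3, with adjusted p of up to 0.0918.

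Of 19938 genes, 670 were higher and 1022 lower on the arrays labelled knockout at a limma adjusted p under 0.05, and 30 and 147 of them by at least 1 on log2. Predicted or clone symbols made up 10 and 49 of the called genes. The 2 groups did not overlap in 27.6% of all genes, against 10% by chance. The numbers higher and lower were 310 and 601 without knockout 3, 206 and 389 without control 1, 144 and 370 without control 2, and 158 and 301 without control 3. In all 6 such fits 407 genes kept their calls, 129 higher and 278 lower. In the 4 female pools alone 114 genes were higher and 84 lower. The arrays labelled knockout were ranked as by the ciliated marker mean in 504 of 955 lower genes outside the ciliated and axonemal ones (52.8%). The same ranking was seen in 6.42% of higher genes and in 16.9% of all genes outside these, called or not, a count chosen after the values were seen. On the main axis of variation between arrays (principal component 1, 51.1% of variance), knockout 1, 2 and 3 read 12.7, 16.1 and 22.45. Control arrays read -14.98 or less. The ranking is thus also that of distance from the controls. Lower genes can share it without any tie to ciliated cells. The reverse ranking was not counted among higher genes. Each remark that a gene ranked these arrays as the ciliated mean did has this limit.

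Genes of fatty acid synthesis rose as a group, with 11 of 20 measured members higher, 0 lower and 9 not past the limma threshold (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.16e-06). With an estimated correlation the camera adjusted p = 0.272 for this list. The fatty acid desaturase Fads2 rose by 0.63 ± 0.06, fatty acid synthase Fasn by 0.50 ± 0.05, and the acetyl-CoA carboxylases Acacb and Acaca by 0.56 ± 0.06 and 0.47 ± 0.08. Cholesterol synthesis genes also rose as a group, with 6 of 20 higher and 0 lower (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.65e-06, and adjusted p = 0.384 with an estimated correlation). Tm7sf2 rose by 0.65 ± 0.07, Dhcr7 by 0.55 ± 0.09, Nsdhl by 0.50 ± 0.08 and Hsd17b7 by 0.49 ± 0.10. Pmvk (0.60) and Lss (0.58) were also called. Ebp (-0.40) and Srebf2 (-0.017) had negative differences without a call. Member counts fell to 3 for fatty acid synthesis without knockout 3, control 1 or control 2 and 4 without control 3. With the replicate number as a block 7 fatty acid synthesis members were called. For cholesterol synthesis they were 3 without knockout 2 or control 3, 2 without control 2 and 1 without knockout 3 or control 1, while 1 member was lower without knockout 1. With the block they were 8.

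Of 14 measured genes of cholesterol efflux and liver X receptor targets, 3 rose and 1 fell, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.145). The lipoprotein receptor Scarb1 rose by 0.63 ± 0.07, the lysophospholipid acyltransferase Lpcat3 by 0.50 ± 0.05 and the cholesterol carrier Npc2 by 0.36 ± 0.06, while the phospholipid transfer protein Pltp fell by 0.88 ± 0.16. Genes of phospholipid synthesis went both ways, with 4 of 26 higher and 3 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.365). Lpcat3 and Agpat2 (0.41 ± 0.06) rose, and Lpcat4 (-0.61 ± 0.11) and Pcyt1a (-0.51 ± 0.10), the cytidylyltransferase of phosphatidylcholine synthesis, fell. Pltp, Lpcat4 and Pcyt1a ranked the arrays labelled knockout as the ciliated marker mean did. The phospholipid counts were 2 higher and 0 lower without knockout 3, control 1 or control 2 and 1 and 0 without control 3. Lpin2 (0.37 ± 0.13) was not called, but passed with the replicate number as a block (adjusted p = 0.0353), where Lpcat1 did not. Without knockout 1, 2 efflux genes were lower. Agpat2 lost its call without control 3 (adjusted p = 0.0572). Npc2, Lpcat4 and Pcyt1a lost theirs without knockout 3 or any 1 control array, with adjusted p of up to 0.0959. Pltp lost its call without control 1 (adjusted p = 0.0825), control 2 (0.0850) or control 3.

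Of 13 genes for surfactant proteins and lamellar bodies, the organelles that store surfactant, 2 rose, 0 fell and 11 did not pass (5 higher adjusted over the list alone). The list passed camera with a mean of 0.11 on log2 (adjusted p = 0.0117, and adjusted p = 0.384 with an estimated correlation). The 2 were Lamp3 (0.32 ± 0.07, adjusted p = 0.0337) and the acyltransferase Lpcat1 (0.22 ± 0.05, adjusted p = 0.0405), and Ctsh and Napsa stood at 0.33 ± 0.09 and 0.17 ± 0.05 without passing. Neither Lamp3 nor Lpcat1 was called without knockout 3 or any 1 control array, nor Lpcat1 without knockout 1, with adjusted p of up to 0.168. With the replicate number as a block their adjusted p was 0.0522 and 0.0765. Surfactant protein genes lay near the top of the array scale, with Sftpc, chosen after its values were seen, at 13.15 ± 0.04 and 13.15 ± 0.01 (SD, n = 3 each).

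Type II cell identity genes showed no common direction, with 2 of 20 higher (2 higher and 1 lower adjusted over the list alone) and camera adjusted p = 0.982. Their mean was 0.016 and their median -0.017, and the camera direction was down. The alarmin Il33 rose by 0.72 ± 0.11 and the chitinase-like Chil1 by 0.26 ± 0.05, while Krt18 stood at -0.36 ± 0.09 and Cdh1 at -0.14 ± 0.05 without passing. Krt18 was called without knockout 1 (adjusted p = 0.00733) and with the replicate number as a block (0.0295). Chil1 was not called with the replicate number as a block (adjusted p = 0.0534). Without control 2 or control 3 neither Il33 nor Chil1 was called, nor Chil1 without knockout 3 or control 1, with adjusted p of up to 0.0953.

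Lysosomal genes rose as a group, with 3 of 24 higher and 0 lower (6 higher adjusted over the list alone; camera adjusted p = 0.000483, and adjusted p = 0.384 with an estimated correlation). These were Npc2, the hexosaminidase chain Hexa (0.35 ± 0.05) and the sialidase Neu1 (0.28 ± 0.05). Neu1 was not called with the replicate number as a block (adjusted p = 0.0522). Without knockout 3 or any 1 control array only Hexa of the 3 was called, and without knockout 2 the list had 4 higher and 1 lower. Secretory exocytosis genes did not move as a group (1 of 21 higher, also adjusted over the list alone; camera adjusted p = 0.342), with Rab27a at 0.31 ± 0.05. Without knockout 2, 2 of them passed. Rab27a lost its call without knockout 3 or any 1 control array (adjusted p of up to 0.0773). Of 27 adhesion receptors other than Gpr116, 0 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.291). They were Adgrv1 (-0.78 ± 0.08), Celsr2 (-0.31 ± 0.06), Celsr1 (-0.32 ± 0.06) and Adgre5 (-0.46 ± 0.11). Without knockout 1 another member was higher. Adgrv1 alone of these was called without knockout 3 or any 1 control array, and Adgre5 was not called with the replicate block (adjusted p = 0.0803). Of 19 Gq signalling genes 1 passed, also adjusted over the list alone, the G protein subunit Gna14 at -0.88 ± 0.12 (camera adjusted p = 0.735). With the replicate block Rgs4 (0.30 ± 0.10, adjusted p = 0.126) and, among exocytosis genes, Stx3 (0.27 ± 0.08, adjusted p = 0.114) also passed, at 0.0485 and 0.0461. The Gq genes called were 1 higher and 3 lower without knockout 2 and 1 and 1 without knockout 1. Gna14 ranked the arrays labelled knockout as the ciliated marker mean did, and none of the 4 adhesion receptors did so.

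Proliferation genes were higher as a group. Of 21 measured, 10 rose and 0 fell (all 21 higher adjusted over the list alone; camera adjusted p = 4.11e-12, and adjusted p = 0.384 with an estimated correlation). The spindle checkpoint kinase Bub1 rose by 0.90 ± 0.14, Prc1 by 0.92 ± 0.18, Cdk1 by 0.78 ± 0.15 and Rrm2 by 0.61 ± 0.11. The mean of the 21 genes was 8.83, 8.31 and 8.63 on the arrays labelled knockout and 8.06, 7.89 and 8.04 on the control arrays. The number of members called was 16 with the replicate number as a block, 18 without knockout 2 and 1 without knockout 3. It was 0 by limma without any 1 control array, where 17 to 21 members had an unadjusted p under 0.05.

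Cytokine and NF-kappaB target genes rose as a group, with 6 of 22 higher and 0 lower (10 higher adjusted over the list alone; camera adjusted p = 4.95e-06, and adjusted p = 0.272 with an estimated correlation). Besides Saa3, the iron-binding lipocalin Lcn2 rose by 0.91 ± 0.07, the macrophage growth factor Csf2 by 0.59 ± 0.05 and the NF-kappaB inhibitor Tnfaip3 by 0.57 ± 0.08. The members called were 4 without control 2 or control 3, and 7 with the replicate number as a block, where Cxcl10 (0.37 ± 0.12, adjusted p = 0.114) also passed, at 0.0228. Interferon response genes were higher as a list, with 2 of 18 higher, also adjusted over the list alone (camera adjusted p = 0.00149, and adjusted p = 0.384 with an estimated correlation). Ifit1 rose by 0.59 ± 0.07 and Zbp1 by 0.39 ± 0.08, and Rsad2 stood at 1.18 ± 0.39 (adjusted p = 0.128, and 0.0113 with the replicate block). Without knockout 1, 1 member of this list was lower. Zbp1 was not called without knockout 1 or any 1 control array (adjusted p of up to 0.133). Of 22 endoplasmic reticulum stress genes 1 passed, also adjusted over the list alone, the mannosidase-like Edem1 at 0.29 ± 0.06 (camera adjusted p = 0.0864). Without knockout 1, 3 of these were higher. Edem1 was not called with the replicate block (adjusted p = 0.0619) nor without knockout 3 or any 1 control array (up to 0.107).

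Immediate early genes, which respond within minutes to stimulation and to cell dissociation, were lower as a group. Of 20 measured, 2 fell and 0 rose (5 lower adjusted over the list alone; camera adjusted p = 0.000152, and adjusted p = 0.384 with an estimated correlation). Nr4a1 fell by 0.76 ± 0.10 and Egr1 by 0.56 ± 0.09, the latter not called without control 1 or control 3 (adjusted p of up to 0.0685). With the replicate number as a block 3 members were lower and 1 higher, since Atf3 (-0.39 ± 0.10) and the heat shock gene Hspa1a (0.68 ± 0.22) then passed (adjusted p = 0.0295 and 0.0413). Without knockout 2, 5 members were lower, and without knockout 1, 2 were lower and 1 higher. Oxidative stress and NRF2 targets were lower as a list, with 3 of 18 lower and 1 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.0243, and adjusted p = 0.465 with an estimated correlation). The metallothionein Mt2 rose by 1.36 ± 0.18, while the glutathione transferases Gsta3 and Gstm1 fell by 0.86 ± 0.18 and 0.72 ± 0.15 and the superoxide dismutase Sod1 by 0.36 ± 0.07. Gsta3 and Sod1 stood highest on knockout 1 and lowest on knockout 3, as did the ciliated marker mean given below. With the replicate block 5 members were lower and 2 higher, and without knockout 1, 7 were lower. The list call was lost without knockout 3 (mean -0.084, adjusted p = 0.0941) and without control 1 (mean -0.14, adjusted p = 0.0785). None of Gsta3, Gstm1 and Sod1 was called by limma without any 1 control array, nor Sod1 without knockout 2 or knockout 3, nor Mt2 without control 3, with adjusted p of up to 0.125.

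**Figure D2:**
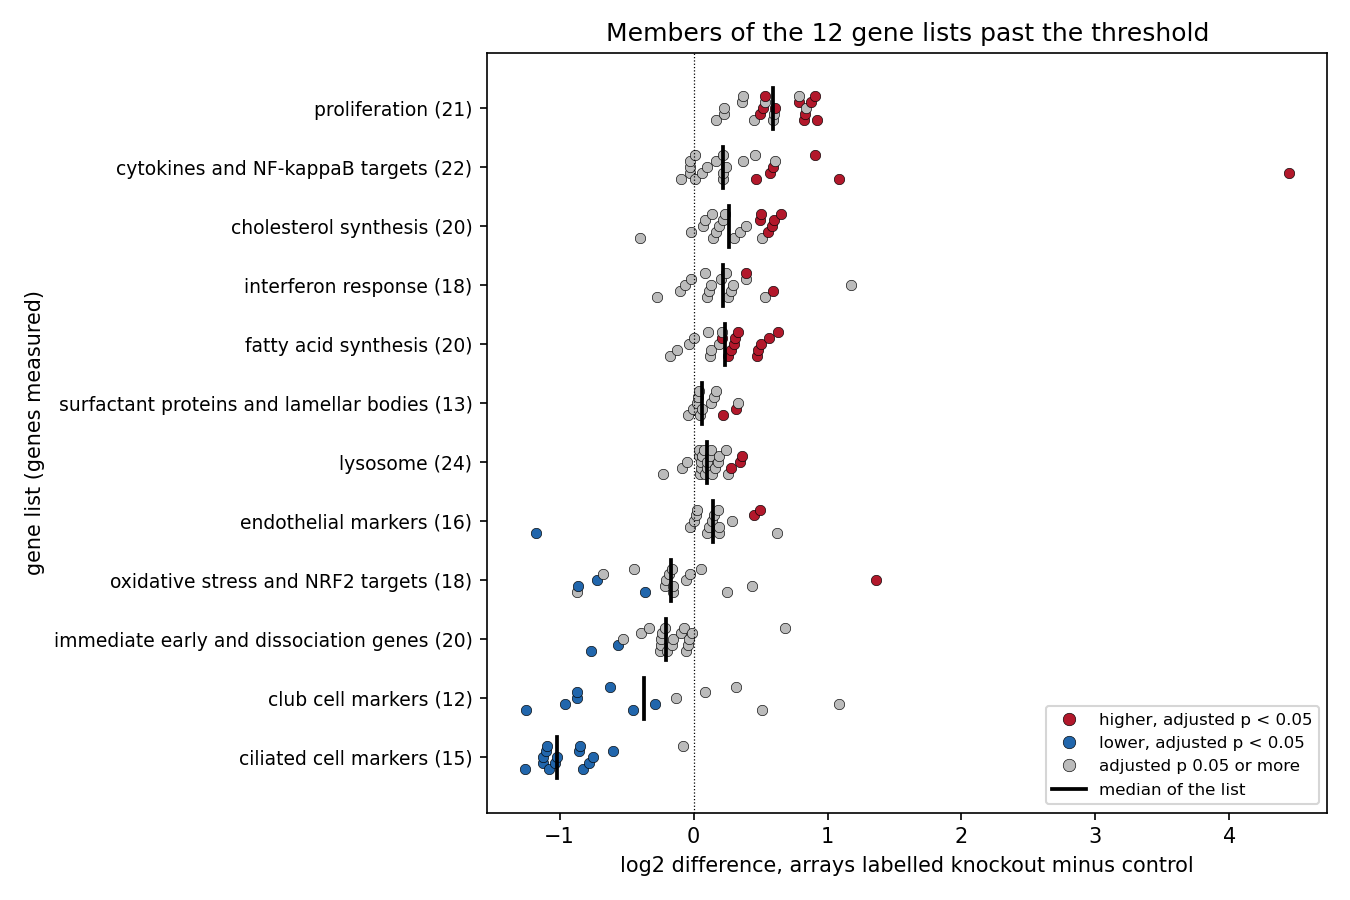
Log2 differences, arrays labelled knockout minus control, of the members of the 12 gene lists past the camera threshold, 1 dot per gene and a bar at the list median, with the number of genes measured in brackets. The median was -1.02 for ciliated cell markers and 0.59 for proliferation genes, and with an estimated correlation 0 of these lists passed.

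Most markers of airway cells were lower on the arrays labelled knockout. Of 15 ciliated cell markers 14 fell, also adjusted over the list alone, with a median of -1.02 (camera adjusted p = 1.32e-13, and adjusted p = 0.384 with an estimated correlation). Hydin fell by 1.26 ± 0.14, the dynein chain Dnah5 by 1.13 ± 0.14 on log2. Cdhr3 was 2.14-fold and Ccdc39 2.15-fold lower (log2 SE 0.14 and 0.15). The mean of the 15 genes was 8.79, 8.38 and 8.23 on the arrays labelled knockout against 9.39, 9.34 and 9.38. The members called were 9 without knockout 3, 8 without control 1, 5 without control 2 and 3 without control 3, where Ccdc39 had adjusted p = 0.0505. In the female pools alone 0 of the 15 passed by limma, 14 had an unadjusted p under 0.05, and the median was -0.97. Of 12 club cell markers 7 fell (8 lower adjusted over the list alone; camera adjusted p = 0.000173, and adjusted p = 0.384 with an estimated correlation). The secretoglobin Scgb3a2 fell by 0.96 ± 0.09, Aldh1a1 by 0.62 ± 0.11 and Cckar by 1.25 ± 0.22, and Lypd2 stood at -0.87 ± 0.09. Scgb1a1 stood at -0.13 without passing. Scgb3a1 (0.083), Reg3g (1.09), Bpifa1 (0.51) and Muc5b (0.32) had positive differences without a call. The club markers called were 4 without knockout 3 and 2 without any 1 control array, and Scgb3a2 and Lypd2 kept their calls whichever array was left out. Cyp2f2 (-0.29 ± 0.07, adjusted p = 0.0467) did not pass with the replicate number as a block (0.0657). Of the 7 club markers 4 ranked the arrays labelled knockout as the ciliated mean did.

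Endothelial markers were higher as a list, with 2 of 16 higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.0117, and adjusted p = 0.384 with an estimated correlation). Esam rose by 0.50 ± 0.05 and Pecam1 by 0.45 ± 0.07, while the growth factor receptor Kdr fell by 1.18 ± 0.20. Among genes above the 60th percentile of expression the list mean was -0.0525 (adjusted p = 0.529). Kdr was not called without any 1 control array and Pecam1 without control 2 or control 3 (adjusted p of up to 0.0706). Type I cell markers did not move as a group (1 of 16 higher, 1 lower, 2 and 3 adjusted over the list alone; camera adjusted p = 0.470), with Ager at 0.22 ± 0.05 and Igfbp6 at -0.79 ± 0.14. Ager was not called with the replicate block (adjusted p = 0.0824), nor Ager or Igfbp6 without any 1 control array, nor Ager without knockout 1 or knockout 3 (up to 0.153). Without knockout 1, 5 type I markers were higher and 1 lower. Kdr and Igfbp6 ranked the arrays labelled knockout as the ciliated marker mean did.

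Markers of blood and stromal cells did not pass camera. Of 18 alveolar macrophage markers 1 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.568), with the lipopolysaccharide receptor Cd14 at 1.07 ± 0.09 and Plet1, which ranked the arrays labelled knockout as the ciliated mean did, at -0.60 ± 0.11. Plet1 was not called without knockout 3 or any 1 control array (adjusted p of up to 0.101). Of 12 neutrophil markers only Retnlg passed, also adjusted over the list alone (0.58 ± 0.13; camera adjusted p = 0.365). Mmp8 (1.04 ± 0.42, limma adjusted p = 0.200) passed without knockout 1 (adjusted p = 0.0267). Of 17 lymphocyte markers 0 passed by limma, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.318). Of 16 fibroblast and smooth muscle markers only Postn passed, also adjusted over the list alone (0.89 ± 0.20; camera adjusted p = 0.470), and with the replicate block Postn did not pass (adjusted p = 0.0523) while Acta2 (0.42 ± 0.16, adjusted p = 0.193) and Myh11 (0.48 ± 0.20, adjusted p = 0.216) did, at 0.0444 and 0.0293. Of 5 red cell and platelet markers 1 rose, Pf4 at 0.43 ± 0.10 (2 adjusted over the list alone), and the list had camera adjusted p = 0.121, or 0.0164 with the replicate number as a block, where Slc4a1 also passed (1.30 ± 0.41; adjusted p = 0.112, and 0.00949 with the block). Pf4 was not called without knockout 2, knockout 3 or any 1 control array, Retnlg without knockout 1, knockout 2 or any 1 control array, and Postn without knockout 1, knockout 3, control 2 or control 3, with adjusted p of up to 0.144. Without knockout 2, 1 fibroblast marker was lower.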

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

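Of the 13767 probe sets without a single gene symbol, which the gene-level comparison did not use, 97 were higher and 117 lower on the arrays labelled knockout when all probe sets were fitted together with limma. Their log2 differences reached 1.91 and -1.24. Past the threshold were 1.55% of these probe sets and 5.08% of those with 1 symbol. With 3 arrays per group, single arrays were not tested as outliers.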

How the results depend on the processing

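The numbers of genes were 670 higher and 1022 lower. No gene called there changed sign in any alternative. In fits without some arrays this was fixed beforehand, since the 2 groups did not overlap in any of the 1692 called genes. Blocks and thresholds do not alter the differences. The counts stayed within 1.5 times under both filters on dim probe sets, the intensity trend, array weights (1000 and 1285), the replicate block (615 and 969), the block on the series of title numbers, quantile normalization (576 and 990), median centring (688 and 914), the mean of probe sets, and the block on sex, which was added after seeing the data. They were 1876 and 1804 with the title number as a random term, where the consensus correlation was -0.513. As the groups share no first title number, neither fit with these numbers separates a batch they may mark from the group. With all probe sets 414 were higher, at an adjusted p under 0.10 the number higher was 1154, and at an unadjusted p under 0.05 with at least 1.5-fold they were 223 and 520. In the female pools alone, also added after seeing the data, they were 114 and 84. Leaving out 1 array gave 144 to 835 higher and 301 to 1265 lower. The cause was not tested. Fewer arrays or more tests leave less power, yet without knockout 2 both counts were above those of the full fit, at 835 and 1055.

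With the replicate number as a block 1331 of the 1692 calls were kept, 361 were lost and 253 other genes gained a call. Among list members 13 lost and 24 gained a call. Besides those in the report, the block ended the calls of Scd1, Scd2, Fads1 and Acsl5, and added Idi1, Fdps, Gsta4, Gpx2, Mt1 and 6 proliferation genes (Top2a, Ccnb2, Birc5, Aurkb, Kif11 and Cenpf). It moved the red cell and platelet list past the threshold (mean 0.45) and changed no other list call.

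P2ry2 kept its direction and call in every alternative. The groups did not overlap for P2ry2 or for Gpr116, so leaving out arrays could not turn either direction. Gpr116 stayed higher in all alternatives, at 0.32 to 0.37 when 1 array was left out, and lost its call there without any control array and in the female pools (0.36, adjusted p = 0.0643).

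With an estimated correlation 0 lists passed camera and 3 had an unadjusted p under 0.05, while fry called 13, of which 11 were called by camera. The list means do not depend on this choice: 0.29 for cholesterol synthesis, -0.91 for ciliated, -0.29 for club and 0.11 for endothelial markers, 0.48 for cytokines, 0.24 for fatty acid synthesis and for interferon response, -0.20 for immediate early genes, 0.11 for lysosome and for surfactant, -0.17 for NRF2 targets and 0.59 for proliferation. Fry added adhesion receptors (-0.049) and cholesterol efflux (0.058) and lost NRF2 targets (-0.17). The 40th percentile filter added adhesion receptors (-0.17), lost endothelial markers (0.087) and turned Gq signalling (-0.040). The 60th percentile filter turned endothelial markers (-0.0525) and Gq signalling (-0.00139), left no neutrophil marker list to test, and lost interferon response (0.31) and surfactant (0.11). Array weights turned Gq signalling (-0.011) and quantile normalization turned type II identity (-0.017). Endoplasmic reticulum stress passed with all probe sets (0.085, adjusted p = 0.0289) and at an adjusted p under 0.10 (0.078). In the female pools Gq signalling (-0.019) and fibroblast markers (-0.065) turned, and lysosome (0.066) and NRF2 targets (-0.16) were lost. Leaving out 1 array gave means of 0.0525 to 0.094 for endoplasmic reticulum stress, which passed without knockout 1 or control 3, and -0.23 to -0.084 for NRF2 targets, lost without knockout 3 or control 1. Means with a changed sign, none past the threshold, ran from -0.11 to 0.19 for fibroblast markers, -0.020 to 0.055 for Gq signalling, -0.032 to 0.18 for lymphocyte markers and -0.019 to 0.057 for type II identity. Among single genes Alas2, never past the threshold, ran from -0.023 to 0.64. Of the values of named genes other than Gpr116 and P2ry2 under these alternatives, 2149 kept direction and side of the threshold, 261 lost and 88 gained a call. The cause was not tested. Camera takes no random term, so the title number was not run that way for lists, and the unadjusted threshold was not applied to them.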

Other observations

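The counts over other splits of the arrays and the fits that left out 1 array or used the replicate block were planned. The tests of explanations in this part, among them the use of the fits without 1 array against a mislabelled array, were chosen after the results were seen, as were the fit of the female pools and the sets of clock, acute phase, imprinted and axonemal genes. Genes of the circadian clock moved apart. Of 10 genes of the phase of Dbp, Dbp included, 8 were lower on the arrays labelled knockout at a limma adjusted p under 0.05, among them Nr1d2 (-1.20 ± 0.16), Per3 (8.17 against 9.18, SE 0.13), Tef (-0.99 ± 0.09) and Nr1d1 (-0.96 ± 0.07). Of 4 genes with the opposite phase, 2 were higher, Nfil3 (0.73 ± 0.08) and Cry1 (0.44 ± 0.08), and Arntl stood at 0.68 ± 0.20 (adjusted p = 0.0887, and 0.0485 with the replicate number as a block). Without any 1 control array 5 of the 10 and 1 of the 4 were called. Of 19 acute phase genes 11 were higher, including Orm1 (1.19 ± 0.13), Itih4 (1.26 ± 0.05) and Cfb (1.15 ± 0.11), and 1, Hp, was lower (-0.46 ± 0.10, not called after median centring or without knockout 2, knockout 3 or any 1 control array). With the block Serpina3n (1.52 ± 0.37), not called without it, also passed, with adjusted p = 0.0278, and without control 2 or control 3 the number higher was 8. Of 15 imprinted genes Meg3 and Nnat were higher (Nnat at 0.38 ± 0.08) and Plagl1 (adjusted p = 0.00187) and Cdkn1c (-0.84 ± 0.13) lower, and only Meg3 and Plagl1 kept their calls in all fits that left out 1 array. The numbers higher and lower were 1 and 2 without knockout 2 or control 3, 2 and 1 without knockout 3, and 1 and 1 without control 1 or control 2. With the block Rian (0.32 ± 0.13, adjusted p = 0.215) passed at 0.0293 and Slc38a4 (-0.42 ± 0.17, adjusted p = 0.201) at 0.0200.

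Genes with ciliary names, called axonemal here after the axoneme, the core of cilia, were lower as a set. Not every name stands for a part of the axoneme, since Ift stands for intraflagellar transport. Of 73 genes with names beginning Cfap, Dnah, Dnai, Drc, Ift, Rsph or Tekt, 57 were lower and 0 higher by limma. Among those outside the ciliated list the number was 53 of 69. These names were chosen after such genes, Cfap44 among them, had been seen to fall, so no test of the set is given. The number of the 73 called was 34 without control 1, 34 without control 2 and 29 without control 3, and 4 in the female pools alone. Quantile normalization and median centring gave 58 and 57. On knockout 1, the lymphocyte genes Cd8a and Cd3g read 7.75 and 6.80, where the other 5 arrays were at 6.18 or less and 5.24 or less. On knockout 2 and knockout 1 the stromal genes Tcf21 (10.04 and 7.74) and Pdgfra (11.08 and 9.12) lay on opposite sides of the control arrays.

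There are 10 ways to split the 6 arrays into 3 and 3, too few for a share under 0.05. The real split, the only 1 with as many, called 1692 genes by limma, and the highest of the other splits 0, with 246 to 1334 genes at an unadjusted p under 0.05 against 4402. The other splits mix the 2 groups, so a difference between the groups, whatever its cause, widens the spread within each set. Few calls there would follow in any case, and the contrast with 0 decides nothing. For lists the real split called 12, again the only 1 with as many, and the highest of the others 9. That one set knockout 1, knockout 2 and control 3 against the rest and parted all 3 numbered pairs, as 4 splits did with the real one included. The list test with its preset correlation thus called lists where limma called no gene.

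The Gpr116 probe set was higher on the arrays labelled knockout. The difference did not rest on a single array, since each array labelled knockout read 11.78 or more and each control array 11.53 or less. With the groups apart, it had to stay positive whichever array was left out (0.315 or more). Leaving out arrays was therefore no further test of a single mislabelled array. None of this shows that each array bears the right label. Probes outside the deleted part could leave a truncated transcript measured, and an exchange of the labels of both groups would turn every direction in the comparison. Neither can be told apart from the other or from a change in the transcript, because the gene had 1 probe set (log2 difference 0.34) whose position in the gene is not known here. A higher level of the remaining transcript through the genotype also stays open and was not tested.

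Most airway marker genes were lower on the arrays labelled knockout. A lower share of ciliated cells in these pools is a candidate explanation of the ciliated part. Of 51 axonemal genes outside the marker list and above the 60th percentile of expression, 94.1% had negative differences, called or not, but such genes had been seen to fall before the names were chosen. It cannot be told apart from a lower ciliary programme within the cells, which predicts the same. A lower share of all airway epithelium also stays open: of 9 club markers with a mean under 12 on log2, 5 were called lower and 4 had positive differences without a call, which decides nothing. Whether either comes from cell isolation or from the genotype was not tested.

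Clock genes moved apart between the groups. A different time of day at cell isolation is a candidate explanation. The 4 genes of the opposite arm (100%) had differences of the other sign than the arm of Dbp, of which 2 passed the threshold, but this largely restates the pattern. It cannot be told apart from an effect of the genotype on the clock, as the labels used here give no hour of isolation.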
